A study of Mus musculus with 12 samples.

How the data were processed

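RNA of 12 tumours, 3 in each of 4 groups, had been measured on Affymetrix arrays. Per the labels' protocols, MC38 cells with an inducible hairpin against Tdo2, APC-WT or APC-KO, had been injected into the cecum of C57BL/6 mice, Dox water had been given to induce the hairpin, RNA had been extracted with Trizol and purified on columns, and biotinylated cRNA had been prepared. The series design speaks of cell lines, while the label of each sample speaks of tumours. Genes of host cells such as Lyz2, Csf1r and Col3a1 had mean log2 values of 13.18, 11.96 and 13.37, so RNA of tumour and host cells was measured together. The labels do not state whether the 3 tumours of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. Tumours with Dox but without the hairpin were not analysed here, so an effect of Dox itself and one of the hairpin were not separated.

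The deposited values are log2 expression values, normalized by the authors. Per the submitters' processing notes MAS5 was used, with no version given; the steps of background correction, scaling and log transform are not given in the sources used here. That the unit is log2 was read from the values, which ranged from 1.86 to 14.16. The plan had allowed for linear values, with a logarithm to be taken, and this step was not needed. Array medians lay between 5.528 and 5.575, no 2 arrays held identical values, and correlations between arrays of a group were between 0.995 and 0.998. For arrays the number of samples limits the precision, and so does signal over background. Genes near the floor can hide a change or its size, though some of them passed.

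The table held 45101 probe sets, of which 64 were controls. With 1 gene symbol there were 34945, with several 932, and with none 9160; and 34741 probe sets were matched to the mouse reference by Entrez identifier for names and gene order. Each of 18193 genes was represented by its probe set with the highest mean over all arrays. Genes were tested where that mean was at or above the median of all non-control probe sets, a log2 value of 5.55, which left 11070 genes and set aside 7123. This floor is a filter on the mean over all arrays and not a measured background, and no detection calls were used here, so a tested gene can lie under it in 1 group. Where all 3 arrays of a group lay under the floor and the other arrays of the comparison did not, a fold is given as a bound, from the mean of the other group against the floor. Where some of the others lay under it too, no fold is given. Such a bound does not include the spread between tumours. This way of giving folds was chosen after the data were seen, and the order and choice of named genes still followed the fitted differences. No further normalization between arrays was applied.

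A group-means model was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend), with statmod 1.5.0 installed, and 5 contrasts were tested, all 2-sided: Dox in APC-WT, Dox in APC-KO, APC-KO versus APC-WT without Dox, the same with Dox, and the interaction of Dox and genotype. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. An exact test of 3 against 3 cannot go below p = 0.1, so single genes were tested only in this model. Data were also simulated from the gene means and residual spread of the arrays, with normal noise independent between genes. In them 200 genes were changed, and the hypoxia genes were lowered by 0.5. A log2 change of 1 was found for 98, 99, 96, 97 and 96% of genes in the order of the contrasts. A change of 0.5 was found for 79, 85, 81, 81 and 53%. False calls made up 2.66, 5.88, 5.61, 5.18 and 3.87% of the calls. The simulation held no outlying arrays and no correlation between genes, so these shares need not hold for the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

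Comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule named Tdo2 and Apc in every comparison; in each comparison the 10 genes that rose most and the 10 that fell most among those that passed and whose 2 groups did not overlap, filled up to 5 per direction with the genes of smallest p; and up to 4 members of each list described, those that passed with the largest change first, then those with the smallest p, then, in lists with no passing member, the member with the highest mean. Unnamed clones and predicted genes were skipped.

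The 32 lists comprised 14 pathway lists: Wnt/beta-catenin targets, tryptophan and kynurenine enzymes and transporters, aryl hydrocarbon receptor targets, glycolysis, oxidative phosphorylation, chemokines and inflammatory cytokines, interferon-stimulated genes, antigen presentation, cell cycle, hypoxia, extracellular matrix and mesenchymal programme, p53 targets, unfolded protein and integrated stress response, and cholesterol biosynthesis. The 18 marker lists were macrophage, neutrophil, T cell, NK and cytotoxic cell, B and plasma cell, dendritic cell, mast cell, endothelial cell, fibroblast, smooth muscle, enteric neuron and glia, cecal epithelium, pancreatic acinar cell, hepatocyte, skeletal muscle, adipocyte, red blood cell, and sex chromosome genes. The 22 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes.

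Each result was recomputed with quantile normalization, with each array centred on its median, with no filter and with a filter at the 75th percentile (a log2 value of 7.81), with the mean of a gene's probe sets, with the replicate number as a block, with only the groups compared, with eBayes without a trend, with array quality weights, and without each array in turn. Leaving out the genes of chromosomes 3 and X was added after the data were seen. The analysis of chromosomal windows of 30 genes was also chosen then. Lists of the same expression levels, drawn at random 2000 times, gave the range set against each block of genes and against the hypoxia list.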

Results

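The series addressed TDO2, the enzyme that opens the ring of tryptophan in the kynurenine pathway, in colon tumours with and without APC, the scaffold protein that holds beta-catenin at low levels. Tumours had been grown in the mouse cecum from MC38 cells, a mouse colon carcinoma line, that carried a doxycycline-inducible hairpin against Tdo2 and were either APC-intact (APC-WT) or APC-deleted (APC-KO). Animals received doxycycline (Dox) in drinking water or none, and 3 tumours per group were profiled on arrays. Differences are on the log2 scale with the standard error of the limma fit, and each is over 3 tumours per group unless stated. The floor of 5.55 is a log2 value set as a filter. Where all 3 arrays of a group lay under it, the fold is given as a lower bound, computed against that floor. It is left out where other arrays of the comparison lay under the floor too. Such a bound is taken from the mean of the other group and does not include the spread between tumours.

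Tdo2 could not be followed on these arrays. Its 3 probe sets had mean log2 values of 2.585, 3.12 and 3.85 over all 12 arrays, all under the floor of 5.55, and the brightest of them differed with Dox by 0.00 ± 0.11 in APC-WT and 0.27 ± 0.11 in APC-KO tumours (adjusted p over all probe sets 0.998 and 0.414). These values do not show whether the hairpin lowered Tdo2. Apc was read by 3 probe sets above the floor. One of them was lower in APC-KO than in APC-WT tumours, by -0.84 ± 0.09 without Dox and -0.94 ± 0.09 with Dox (adjusted p over all probe sets 1.02e-05 and 3.08e-06). Another was lower by -0.41 ± 0.11 and -0.49 ± 0.11 (adjusted p 0.0187 and 0.00647). The brightest, with a mean of 8.39, differed by -0.10 ± 0.07 without Dox and -0.24 ± 0.07 with Dox (adjusted p 0.416 and 0.0443). As the gene tested, that last difference passed with Dox and no longer passed without APC-WT Dox replicate 2 or 3 or APC-KO Dox replicate 1 or 3, with an adjusted p of up to 0.0874. Apc did not pass with Dox in either genotype, at 0.04 ± 0.07 in APC-WT and -0.09 ± 0.07 in APC-KO tumours, and its interaction was -0.13 ± 0.10. The part of Apc that was deleted is not given in the sources used here, so a probe set outside it would check nothing, and RNA of the host's own cells was also measured.

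In APC-KO tumours, most of the genes that changed with Dox were lower. S100a9 and S100a8, which encode the calprotectin subunits abundant in neutrophils, fell by at least 11.2-fold and 8.41-fold (adjusted p 0.0133 and 0.0113). Their APC-KO Dox means of 4.737 and 4.559 lay under the floor on all 3 arrays. The APC-KO no-Dox values were 9.999, 9.512 and 7.605 for S100a9 and 9.352, 9.17 and 7.352 for S100a8. The bounds therefore rest on means that 1 tumour, replicate 3, pulled down. The neutrophil-attracting chemokine genes Cxcl2, at least 5.06-fold and likewise under the floor with Dox, and Cxcl1 (-2.57 ± 0.46) fell as well. The collagenase gene Mmp13 fell by 2.43 ± 0.43, with 2 of 3 APC-KO Dox arrays under the floor. The metallothionein genes Mt2 and Mt1 fell (-1.65 ± 0.25 and -1.53 ± 0.23). Ier3, an immediate early response gene, fell by 1.56 ± 0.24. Ankrd37 and the mitophagy gene Bnip3, both targets of hypoxia-inducible factor, fell (-1.63 ± 0.23 and -1.53 ± 0.21, adjusted p 0.00861 for each). The genes that rose were 4: Ldlrad3 (0.92 ± 0.19), Serpinf1, which encodes the anti-angiogenic factor PEDF (0.78 ± 0.15), Pck2, the mitochondrial phosphoenolpyruvate carboxykinase (0.49 ± 0.10), and Arhgap11a (0.33 ± 0.07). Next in that direction was Ddx39a, at 0.32 ± 0.07 and an adjusted p of 0.0519.

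In total 60 of 11070 genes changed with Dox in APC-KO tumours, 4 higher and 56 lower, and 16 by at least 2-fold in the fit. The count was 29 with eBayes without a trend, 35 with the mean of probe sets and 36 with only the groups compared, and of these 0, 0 and 1 were higher. The values of the 3 Dox and 3 no-Dox tumours did not overlap for 17.7% of genes, where chance gives 10% on average. Genes of the same arrays are not independent, and how far this share varies by chance was not computed. The signal of 18S ribosomal RNA moved with this comparison, with log2 values of 9.804, 10.165 and 9.89 on the APC-KO no-Dox arrays against 9.336, 9.366 and 9.614 on the APC-KO Dox arrays, and no APC-WT array was above 9.606. The count rested on single tumours: it was 0 without APC-KO Dox replicate 3, 4 without APC-KO no-Dox replicate 1, 14 and 94 without APC-KO Dox replicates 2 and 1, and 37 without APC-WT Dox replicate 2. The highest adjusted p with 1 array left out was 0.0583 for Bnip3, 0.0513 for Slc2a1, 0.0816 for S100a9 and 0.141 for Cxcl1, each without APC-KO Dox replicate 3. Bnip3 and S100a9 also lost their calls without APC-KO no-Dox replicate 1, and Cxcl1 without APC-KO no-Dox replicate 1 or 2 or APC-KO Dox replicate 2. Every named gene that passed in this comparison lost its call without APC-KO Dox replicate 3.

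Of the gene lists, hypoxia and glycolysis had the smallest p with Dox in APC-KO tumours. All 18 measured hypoxia genes were below 0, with a median of -0.58, and 7 of them fell while 11 did not pass, or 16 lower when adjusted over the list alone. Those that fell included Slc2a1, the main glucose transporter (-1.22 ± 0.14), and Egln3, an oxygen-sensing prolyl hydroxylase (-0.97 ± 0.13). The list passed with an adjusted p of 3.01e-22, and with adjusted p = 0.0257 with an estimated correlation. Of 19 glycolysis genes 8 fell and 11 did not pass (15 lower when adjusted over the list alone), with a median of -0.41. Examples were Pfkl and Aldoa, a phosphofructokinase and an aldolase (-0.64 ± 0.11 and -0.63 ± 0.10), and Pfkfb3, a regulator of glycolytic flux (-0.60 ± 0.11). That list passed with an adjusted p of 2.98e-18, and with adjusted p = 0.0342 with an estimated correlation. Slc2a1 and Pdk1 are members of both lists. Markers of neutrophils moved with them: 2 of 5, S100a8 and S100a9, fell and 3 did not pass (4 lower when adjusted over the list alone), with a median of -1.08, or -0.341 with no filter on level. Both genes lie on chromosome 3, whose genes were lower as a group in this comparison. Their median was -0.121, far smaller than the fall of these 2 genes.

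By fry 5 lists passed. The other lists that passed in this comparison lost the call with an estimated correlation. Chemokines and inflammatory cytokines had a median of -0.23, and 3 of 18, Cxcl2, Cxcl1 and Cxcl14 (at least 1.59-fold, under the floor with Dox), fell (6 when adjusted over the list alone), with adjusted p = 0.0911 with an estimated correlation. Ccl3 was at -1.24 ± 0.28, with 1 of 3 Dox arrays under the floor, and did not pass. The neutrophil list had adjusted p = 0.0641 with an estimated correlation. Macrophage markers had a median of -0.105, and 1 of 16, the lipopolysaccharide co-receptor Cd14 (-0.48 ± 0.09), fell (4 when adjusted over the list alone), with adjusted p = 0.179 with an estimated correlation; Cd68 and Arg1 were at -0.22 ± 0.05 and -1.33 ± 0.32 without passing. Antigen presentation genes had a median of -0.24 with 0 of 17 passing in limma over all genes and 1 lower when adjusted over the list alone, at adjusted p = 0.461 with an estimated correlation. Tapbp, which loads peptides on MHC class I, was at -0.24 ± 0.06 and B2m at -0.01 ± 0.04. Cell cycle genes had a median of 0.14, with 0 of 24 passing over all genes and 6 higher when adjusted over the list alone, at adjusted p = 0.27 with an estimated correlation. The mitotic regulators Foxm1 and Aurkb were at 0.26 ± 0.07 and 0.28 ± 0.08. Without APC-KO no-Dox replicate 2 the chemokine median was -0.346 and the cell cycle median 0.089, with the calls kept, and the number of lists was 11 without APC-KO no-Dox replicate 1 or APC-KO Dox replicate 2.

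**Figure D1:**
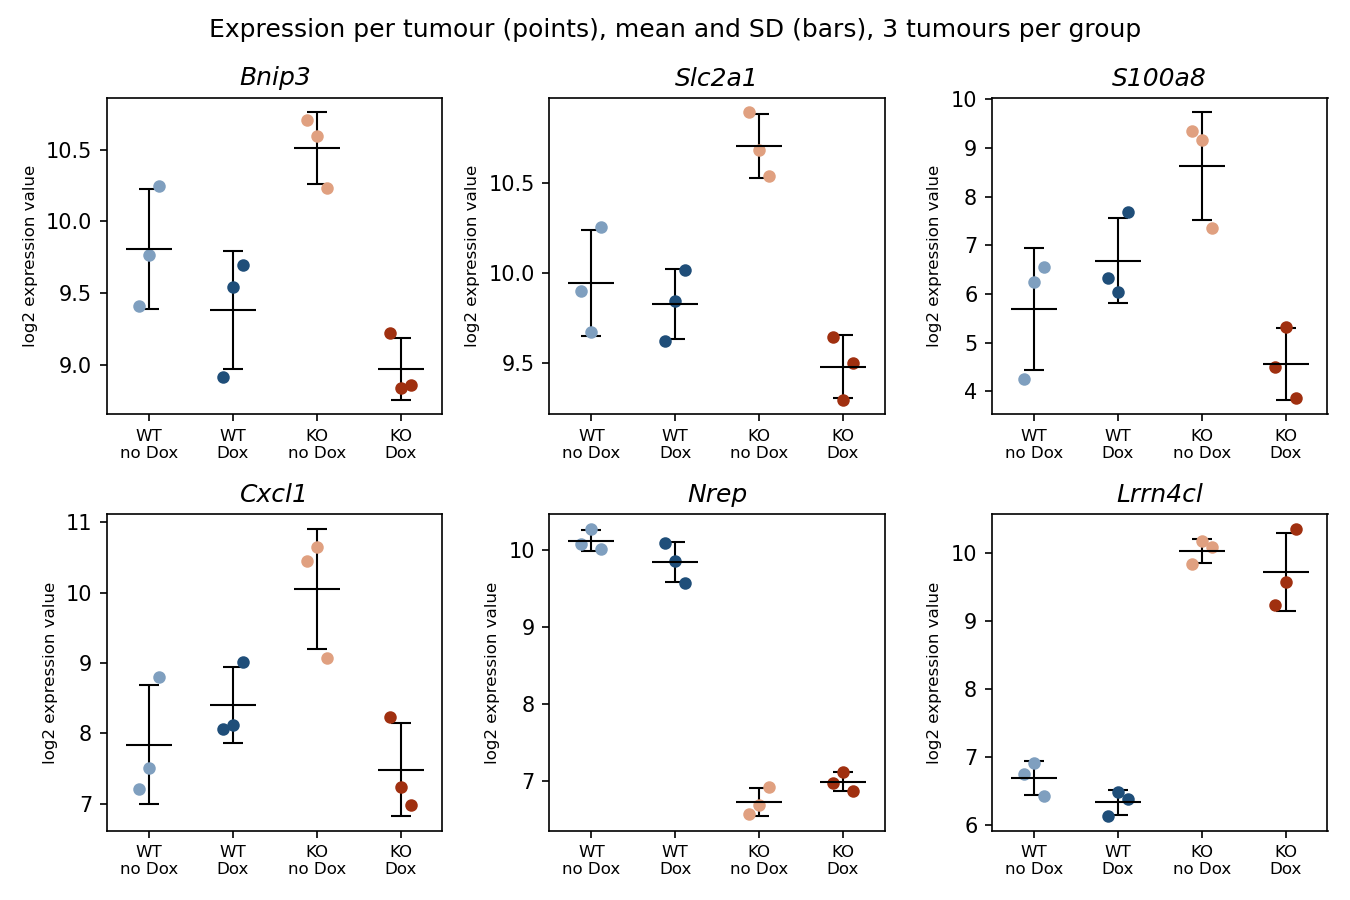
Log2 expression values of 6 genes in each tumour (points), with the group mean and standard deviation (bars), 3 tumours per group. Bnip3, Slc2a1, S100a8 and Cxcl1 were lower with Dox in APC-KO tumours, where the 3 values of S100a8 lay under the floor of 5.55, while Nrep and Lrrn4cl separated the genotypes with and without Dox.

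In APC-WT tumours, few single genes passed with Dox, though differences over all tested genes were no smaller than in APC-KO tumours. In limma the unadjusted p was under 0.05 for 1716 genes in APC-WT and 1446 in APC-KO tumours. The median absolute log2 differences were 0.081 and 0.0735. Ms4a4d, a gene of the membrane-spanning 4A family, fell by 1.82 ± 0.24, with 1 of 3 Dox arrays under the floor, and Ccng2, a FOXO-regulated cyclin gene linked to cell cycle arrest, fell by 0.76 ± 0.09 (adjusted p 0.0146 and 0.00893). Eif1ad rose by 0.39 ± 0.05 (adjusted p 0.0146). Among genes that did not pass, the next higher were Rrp1b, Rsl1d1, Bysl and Socs5, between 0.33 and 0.39, the first 3 of them nucleolar or ribosome assembly genes. The next lower were Txnip (-0.67 ± 0.10, adjusted p 0.0532), Fzd6 (-0.35 ± 0.06) and Wwp2 (-0.38 ± 0.07). The count of 3 genes of 11070 rested on single tumours: it was 0 without APC-WT no-Dox replicate 1 or 2 or APC-WT Dox replicate 1 or 2, 1 without APC-WT Dox replicate 3, 8 without APC-KO no-Dox replicate 2, and 417 without APC-WT no-Dox replicate 3. It was 0 with the mean of probe sets, 18 with only the groups compared and 653 with array quality weights. The highest adjusted p, each without APC-WT Dox replicate 1, was 0.0952 for Ccng2, 0.1503 for Eif1ad and 0.1435 for Ms4a4d. The 2 groups did not overlap for 21.3% of genes, where chance gives 10% on average. The Gapdh control signal, 3' minus 5' on the log2 scale, also separated these groups. It was -0.092, -0.116 and -0.115 on the APC-WT no-Dox arrays against -0.188, -0.158 and -0.163 on the APC-WT Dox arrays. That of Actb overlapped, and a link to the results was not tested.

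Of the lists, 10 passed with Dox in APC-WT tumours, none of them with an estimated correlation, where the smallest adjusted p was 0.5345, and none by fry. No member of these lists passed over all genes in limma, where 1716 of 11070 genes had an unadjusted p under 0.05. Interferon-stimulated genes had a median of -0.49 with all 21 members below 0 (13 lower when adjusted over the list alone), among them Stat2 (-0.60 ± 0.14) and Gbp3 (-0.54 ± 0.16). Extracellular matrix genes had a median of -0.15 (4 lower when adjusted over the list alone), with Tnc, the matrix glycoprotein tenascin C, at -1.12 ± 0.21. Hypoxia genes had a median of -0.24 (1 lower when adjusted over the list alone) and glycolysis genes -0.12 (2 lower), with Pdk1 at -0.41 ± 0.11 in both. T cell markers had a median of -0.385 (1 lower when adjusted over the list alone; Icos -0.46 ± 0.13). Antigen presentation genes were at -0.17 (0 when adjusted over the list alone; Tap1 -0.31 ± 0.11). Cell cycle genes were at -0.11 (1 lower when adjusted over the list alone; Cenpf -0.28 ± 0.06). Cholesterol biosynthesis genes had a median of 0.29 (Hsd17b7 0.48 ± 0.15), unfolded protein and integrated stress response genes 0.17 (Psat1 0.35 ± 0.12), and oxidative phosphorylation genes 0.06 (Ndufb5 0.09 ± 0.04), each with 0 when adjusted over the list alone. The calls of glycolysis, hypoxia and T cell markers ended without APC-WT no-Dox replicate 3 (adjusted p 0.281, 0.281 and 0.279, with medians of -0.063, -0.172 and -0.248), that of antigen presentation without the same array or APC-WT Dox replicate 1 (0.159 and 0.1203, the latter with a median of -0.055), and that of cholesterol biosynthesis without APC-WT no-Dox replicate 2 (0.0859, with a median of 0.083). Array quality weights ended the calls of glycolysis, antigen presentation and T cell markers (medians of -0.065, -0.034 and -0.245). Medians that moved by over 1.5 times with the call kept were those of antigen presentation without APC-WT no-Dox replicate 1 or 2 (-0.077 and -0.286), extracellular matrix genes without APC-WT no-Dox replicate 1 (-0.094), stress response genes without APC-WT no-Dox replicate 2 (0.105), oxidative phosphorylation genes without APC-WT Dox replicate 1 (0.039), and cholesterol biosynthesis genes with the mean of probe sets (0.187).

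**Figure D2:**
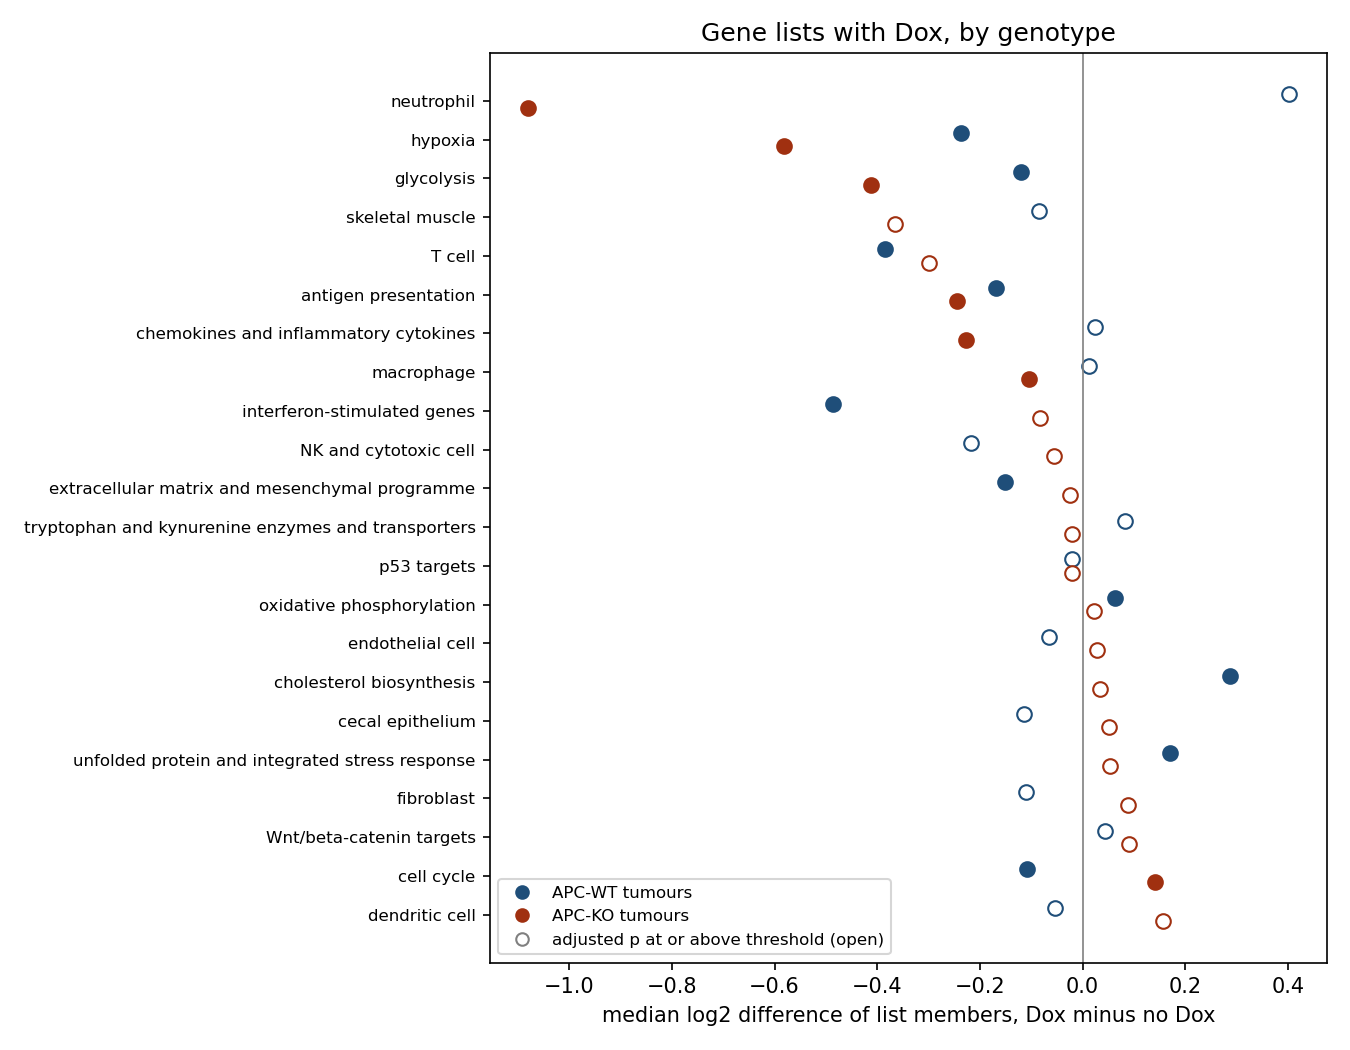
Median log2 difference, Dox minus no Dox, of the tested members of each gene list in APC-WT (blue) and APC-KO (red) tumours; filled points passed an adjusted p of 0.05 with the preset correlation and open points did not. The neutrophil list stood at -1.08 in APC-KO and 0.40 in APC-WT tumours, and hypoxia at -0.58 and -0.24.

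Whether Dox went with different changes in the 2 genotypes was tested as an interaction. No single gene passed in limma: 0 of 11070 genes changed, 1312 had an unadjusted p under 0.05, and the smallest adjusted p was 0.129. The genes of smallest p, 5 in each direction, were, among those lower, S100a9 and S100a8, Slc2a1 (-1.11 ± 0.20), the histone gene H2ac19 (-0.98 ± 0.18) and Eif1ad (-0.41 ± 0.07), and, in the other direction, Cdh26 (1.01 ± 0.19), Serpinf1 (0.99 ± 0.21), Frk (0.64 ± 0.13), Trmt2b (0.47 ± 0.10) and Arhgap11a (0.46 ± 0.09). S100a9 and S100a8 lay under the floor on all 3 APC-KO Dox arrays and on 1 APC-WT no-Dox array, so no size is given for them. The same holds for Cxcl2, with 1 APC-WT array under the floor without Dox and 1 with Dox. Cxcl1 was at -3.13 ± 0.65, and Gzmd and Gzmf at -4.27 ± 0.88 and -3.38 ± 0.73 with 2 of 3 APC-KO Dox arrays under the floor. For Gzmd, APC-KO no-Dox replicate 2 lay under it too. With the APC-KO Dox values under the floor raised to it, Gzmd and Gzmf were at -3.151 and -2.659. Cxcl1, Cxcl2, Gzmd and Gzmf each had a higher p than the 5 lower genes named above. The count was 118 without APC-WT no-Dox replicate 3, 1 without APC-KO no-Dox replicate 1 and 13 with array quality weights.

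By list, 9 passed for the interaction with the preset correlation, none of them with an estimated correlation (smallest adjusted p 0.146) and none by fry. The medians were -0.395 for hypoxia, -0.27 for glycolysis, -0.30 for chemokines and inflammatory cytokines, -1.48 for neutrophil markers, -0.21 for macrophage markers, -0.28 for cholesterol biosynthesis, 0.26 for the cell cycle, 0.395 for interferon-stimulated genes and 0.13 for fibroblast markers. Adjusted over the list alone, 9 hypoxia, 7 glycolysis, 4 chemokine, 3 neutrophil and 3 macrophage genes were lower, and 5 cell cycle and 3 fibroblast genes were higher. Members included Ankrd37 (-1.24 ± 0.32), Pgam1 (-0.27 ± 0.07), Cd14 (-0.65 ± 0.13), Hsd17b7 (-0.73 ± 0.21), Foxm1 (0.42 ± 0.10), Irf7 (1.12 ± 0.35) and Col1a1 (0.49 ± 0.13), none of which passed. With 1 array left out, the highest adjusted p reached 0.0839 for interferon-stimulated genes (without APC-WT Dox replicate 1; 0.0679 without APC-KO Dox replicate 1). Cholesterol biosynthesis lost its call without APC-WT no-Dox replicate 2 (0.338, with a median of -0.041), APC-WT Dox replicate 1 (0.0552), APC-KO no-Dox replicate 1 (0.262, with a median of -0.101) or APC-KO Dox replicate 2 (0.160, with a median of -0.121). Fibroblast markers lost theirs without APC-WT no-Dox replicate 1 (0.0989), APC-WT Dox replicate 1 (0.0552), or APC-KO no-Dox replicate 2 or 3 (0.1125 and 0.0820). Array quality weights ended the calls of interferon-stimulated genes and fibroblast markers (0.1466 and 0.0655), and the 75th percentile filter that of cholesterol biosynthesis (0.0795). Without APC-WT no-Dox replicate 1 or APC-KO no-Dox replicate 2 the interferon median was 0.22 or 0.176. It was 0.259 and the fibroblast median 0.217 at the 75th percentile filter, the hypoxia median was -0.594 with the mean of probe sets, and the neutrophil median was -0.286 with no filter on level, each with the call kept.

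APC-KO and APC-WT tumours without Dox differed in many genes. This comparison and that of Dox in APC-KO tumours share the 3 APC-KO no-Dox arrays, and likewise it shares the APC-WT no-Dox arrays with Dox in APC-WT. Higher in APC-KO tumours were Lrrn4cl (3.33 ± 0.22, or 10.0-fold), S100a9 and S100a8 (3.13 ± 0.70 and 2.94 ± 0.64), Cxcl1 and Cxcl2 (2.21 ± 0.46 and 2.09 ± 0.54), Neto2 (2.07 ± 0.36), the arsenic methyltransferase gene As3mt (1.97 ± 0.19), the prostacyclin synthase gene Ptgis (at least 2.93-fold), Angptl7 (1.79 ± 0.24) and the circadian transcription factor gene Hlf (1.76 ± 0.14). Of the 3 APC-WT no-Dox arrays, all lay under the floor for Ptgis, and 1 for S100a9, S100a8, Cxcl2 and As3mt. Lower were Nrep (-3.39 ± 0.12, or 10.5-fold), the membrane skeleton gene Epb41l3 (-3.03 ± 0.12), Ms4a4d (at least 4.48-fold), the Wnt inhibitor gene Apcdd1 (-2.41 ± 0.23), Chst15 (-2.27 ± 0.12), Cd99 (-2.17 ± 0.09), Adamts9 (-2.08 ± 0.10), Arap2 (at least 2.6-fold), Mgp (-1.91 ± 0.30) and the immunoglobulin A heavy chain gene Igha (-1.88 ± 0.36). Ms4a4d and Arap2 lay under the floor on all 3 APC-KO no-Dox arrays, and Epb41l3 on 1. The APC-KO no-Dox arrays also had the highest 18S ribosomal RNA signal, with log2 values from 9.804 to 10.165 against 9.463 to 9.59 on the APC-WT no-Dox arrays. The Gapdh control signal, 3' minus 5', was -0.184 to -0.154 on the APC-KO no-Dox arrays against -0.116 to -0.092 on the APC-WT no-Dox arrays. That of Actb overlapped. In total 2753 of 11070 genes changed, 1525 higher and 1228 lower, and 103 by at least 2-fold. Groups did not overlap for 37.2% of genes, where chance gives 10% on average. Of these, Cxcl2 lost its call without APC-WT no-Dox replicate 1 or APC-KO no-Dox replicate 1, with an adjusted p of up to 0.0623.

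Interferon-stimulated, T cell, NK and cytotoxic, antigen presentation and cell cycle genes were lower as lists in APC-KO tumours without Dox with the preset correlation, and neutrophil markers and hypoxia genes higher. Each had adjusted p = 0.7184 with an estimated correlation, so none passed there. Macrophage markers (median 0.079; 3 rose) and chemokines and inflammatory cytokines (median 0.008; 5 rose and 1 fell) did not pass as lists. Interferon-stimulated genes had a median of -0.55, and 12 of 21 fell (15 when adjusted over the list alone), among them Usp18 (-1.16 ± 0.28), Stat2 (-0.93 ± 0.14) and Irf7 (-0.90 ± 0.25). Of 7 T cell markers 6 fell (6 when adjusted over the list alone; median -0.69), including Cd8b1 (-1.05 ± 0.20) and Cd3g (-0.97 ± 0.23). Of 7 NK and cytotoxic cell markers 5 fell (5 when adjusted over the list alone; median -0.74), including the granule genes Gzmb (-0.999 ± 0.282) and Nkg7 (-0.88 ± 0.16). Of 17 antigen presentation genes 8 fell (8 when adjusted over the list alone; median -0.215), including Nlrc5, the transactivator of MHC class I (-0.70 ± 0.12), and Tap1 (-0.58 ± 0.11). Of 24 cell cycle genes 5 fell and 1 rose (8 and 1 when adjusted over the list alone; median -0.13), including Cenpf (-0.47 ± 0.06) and Ccnb2 (-0.35 ± 0.05). In the other direction, 8 of 18 hypoxia genes rose (9 when adjusted over the list alone; median 0.31), including P4ha2 (0.82 ± 0.22) and Slc2a1 (0.76 ± 0.14), and 3 of 5 neutrophil markers rose (3 when adjusted over the list alone; median 0.41).

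These 7 lists passed with the preset correlation and none with an estimated correlation, where the smallest adjusted p was 0.718; fry called 2 lists, T cell and oxidative phosphorylation, at an adjusted p of 0.0474 each. The hypoxia call ended without APC-WT no-Dox replicate 1 or APC-KO no-Dox replicate 1 (adjusted p 0.160 and 0.0979). That of neutrophil markers ended without APC-WT no-Dox replicate 1 or APC-KO no-Dox replicate 1 or 2 (0.0875, 0.0979 and 0.0666), and that of NK and cytotoxic markers without APC-WT no-Dox replicate 1 or 3 (0.0673 and 0.06185). Median centring ended the calls of hypoxia and neutrophil markers (0.0553 and 0.05096), the 75th percentile filter that of hypoxia (0.153), no filter on level that of neutrophil markers (0.0898, with a median of 0.243), and array quality weights those of neutrophil and of NK and cytotoxic markers (0.118 each). The number of lists was 4 without APC-WT no-Dox replicate 1 and 3 at the 75th percentile filter. The interferon median was -0.337 without APC-KO no-Dox replicate 2 and -0.364 with array quality weights, and the antigen presentation median -0.142 with array quality weights, with the calls kept. Of the genes named for these lists, Irf7, P4ha2 and Gzmb also lost their calls, each without APC-WT no-Dox replicate 1 and at least 1 APC-KO no-Dox replicate: Irf7 without replicate 2 (adjusted p up to 0.0633), P4ha2 without replicate 1 or 3 (up to 0.0715) and Gzmb without replicate 1 or 2 (up to 0.0851).

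Targets of Wnt and beta-catenin did not move as a list with genotype or Dox. Of the 23 listed genes 10 were tested, and the median difference between APC-KO and APC-WT tumours was -0.01 without Dox and 0.05 with Dox (adjusted p 0.573 and 0.699). Apcdd1 was lower in both (-2.41 ± 0.23 and -2.35 ± 0.23), Ccnd1, which encodes cyclin D1, was lower (-0.24 ± 0.04 and -0.22 ± 0.04), and the transcription factor gene Lef1 was higher (0.39 ± 0.09 and 0.48 ± 0.09); adjusted over the list alone, 1 was higher and 2 lower without Dox, and 2 higher and 2 lower with Dox. With Dox the list median was 0.04 in APC-WT and 0.09 in APC-KO tumours (adjusted p 0.573 and 0.136), and the interaction median was 0.04 (0.448), with 0 genes when adjusted over the list alone. The enzymes and transporters of tryptophan and kynurenine metabolism, of which 6 of 18 were tested, did not pass in any comparison. Their adjusted p was 0.436 and 0.491 with Dox in APC-WT and APC-KO tumours, 0.946 and 0.718 between genotypes without and with Dox, and 0.977 for the interaction. Kyat3, a kynurenine aminotransferase, was higher in APC-KO tumours (0.81 ± 0.09 and 0.45 ± 0.09), and Afmid, the kynurenine formamidase, was lower without Dox (-0.44 ± 0.10). Adjusted over the list alone, 1 was higher and 1 lower without Dox, 1 was higher with Dox, and 1 was higher and 1 lower with Dox in APC-WT tumours. The tryptophan transporter genes Slc7a5 and Slc3a2 were at 0.38 ± 0.15 and 0.20 ± 0.09 with Dox in APC-KO tumours without passing.

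With Dox, the genotypes again differed in many genes; this comparison shares arrays with each comparison of Dox. Higher in APC-KO tumours were Lrrn4cl (3.38 ± 0.22), As3mt (2.44 ± 0.19), the ferritin receptor gene Scara5 (2.38 ± 0.16), Ptgis (at least 3.26-fold), Angptl7 (1.96 ± 0.24), Neto2 (1.901 ± 0.36), the planar cell polarity gene Prickle1 (at least 2.89-fold), Hlf (1.83 ± 0.14), Elovl4 (1.71 ± 0.20) and Armcx1 (1.69 ± 0.12). Of the 3 APC-WT Dox arrays, all lay under the floor for Ptgis and Prickle1, and 2 for As3mt, Neto2 and Elovl4. Lower were the granzyme genes Gzmd (-4.21 ± 0.62), Gzmf (-3.50 ± 0.52) and Gzme (at least 3.62-fold), Epb41l3 (-3.35 ± 0.12), Nrep (-2.85 ± 0.12), Apcdd1, Cd99 (-2.32 ± 0.09), S100a9 (at least 2.9-fold), S100a8 (at least 2.19-fold) and Mmp13 (-2.11 ± 0.43). Of the 3 APC-KO Dox arrays, all lay under the floor for Gzme, S100a9 and S100a8, 2 for Gzmd, Gzmf, Epb41l3 and Mmp13, and 1 for Apcdd1. With the APC-KO Dox values under the floor raised to it, Gzmd and Gzmf were at -3.088 and -2.778. In total 2205 of 11070 genes changed, 1320 higher and 885 lower, and 116 by at least 2-fold. Groups did not overlap for 41.4% of genes, where chance gives 10% on average. The Gapdh control signal, 3' minus 5', was -0.156 to -0.111 on the APC-KO Dox arrays against -0.188 to -0.158 on the APC-WT Dox arrays. That of Actb was 0.193 to 0.275 against 0.167 to 0.19. The count was 1325 and 1288 without APC-WT Dox replicate 2 or 3, 1454 without APC-KO Dox replicate 3, and 3510 with array quality weights. S100a9 and S100a8 lost their calls without APC-WT Dox replicate 3 or APC-KO Dox replicate 1 or 3, with an adjusted p of up to 0.140 and 0.141.

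With Dox, T cell, NK and cytotoxic, antigen presentation, chemokine, glycolysis and hypoxia genes were lower as lists in APC-KO tumours with the preset correlation. Each had adjusted p = 0.646 with an estimated correlation, and none passed by fry. Of 7 T cell markers 5 fell (5 when adjusted over the list alone; median -0.76), including Cd3g (-1.04 ± 0.23) and Cd8a (-0.78 ± 0.15). Of 7 NK and cytotoxic markers 3 fell (5 when adjusted over the list alone; median -0.61), including the perforin gene Prf1 (-1.004 ± 0.189, with 2 of 3 APC-KO Dox arrays under the floor), and of 17 antigen presentation genes 8 fell (9 when adjusted over the list alone; median -0.165), including Nlrc5 (-0.61 ± 0.12) and Psmb9 (-0.58 ± 0.10). Of 18 chemokine and cytokine genes 7 fell and 1 rose (7 and 1 when adjusted over the list alone; median -0.26), including Cxcl14 (at least 1.34-fold, under the floor in APC-KO tumours), Ccl3 (-1.08 ± 0.28, with 1 of 3 APC-KO Dox arrays under it) and Cxcl2, which lay under it on all 3 APC-KO and 1 APC-WT Dox arrays. Of 19 glycolysis genes 8 fell (9 when adjusted over the list alone; median -0.20), including Aldoc (-0.70 ± 0.15) and Pfkl (-0.50 ± 0.11), and of 18 hypoxia genes 3 fell (4 lower and 1 higher when adjusted over the list alone; median -0.28), including Ddit4 (-0.80 ± 0.22). Beside these, 3 of 5 neutrophil markers fell (3 when adjusted over the list alone; median -1.24, or -1.13 with values under the floor raised to it), while the list did not pass (adjusted p 0.101).

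These 6 lists passed with the preset correlation and none with an estimated correlation, where the smallest adjusted p was 0.646, or by fry. The number was 3 without APC-WT Dox replicate 3, 12 with no filter on level and 10 with array quality weights. Without that array T cell (adjusted p 0.05295), NK and cytotoxic (0.05295) and hypoxia (0.0558) lost their calls. Hypoxia also lost it without APC-KO Dox replicate 2 (0.0892, with a median of -0.174), and NK and cytotoxic markers without APC-WT no-Dox replicate 3 or APC-KO Dox replicate 3 (0.0580 and 0.0783, with medians of -0.532 and -0.369). The chemokine call ended at the 75th percentile filter (0.068, with a median of -0.132) and that of NK and cytotoxic markers with the mean of probe sets (0.1173). The antigen presentation median was -0.296 without APC-KO Dox replicate 1, -0.277 with array quality weights and -0.25 at the 75th percentile filter, and the T cell median -0.37 with no filter on level, with the calls kept. Without APC-WT Dox replicate 3, Cxcl2, Ccl3 and Ddit4 had an adjusted p of 0.1775, 0.0742 and 0.0766. Cxcl2 also lost its call without APC-WT Dox replicate 1 or APC-KO Dox replicate 2 or 3, and Ccl3 without APC-WT Dox replicate 2 or APC-KO Dox replicate 3.

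The genotype differences without and with Dox, which share no arrays, overlapped. Of the genes higher in APC-KO tumours 796 were called both without and with Dox, against 182 for independent calls, and 559 were lower in both, against 98.2; 3 genes higher and 1 gene lower without Dox were called in the opposite direction with Dox. Over all tested genes the 2 sets of differences had a Pearson correlation of 0.68 and a Spearman correlation of 0.629. These are correlations across genes, which are not independent replicates. Dox in APC-WT and Dox in APC-KO, which also share no arrays, had 0 called genes in common, where independent calls give 0.000361 higher and 0.0101 lower, too few to tell, and their differences had a Pearson correlation of 0.107 and a Spearman correlation of 0.151 across genes.

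Differences between genotypes also followed position on the chromosomes. A block of 95 genes at the distal end of the X chromosome, from Cstf2 to Erdr1, had a median of 0.70 in APC-KO against APC-WT tumours without Dox and 0.77 with Dox, or 1.62-fold and 1.71-fold. In both, 91 of the 95 genes were above 0, and 81 and 88 passed as higher. Armcx1, named above as higher with Dox, and Trmt2b, named for the interaction, belong to this block. The other 232 tested genes of X had medians of -0.03 and 0.00. Chromosome 10 as a whole was lower in APC-KO tumours, with medians of -0.112 and -0.091 and 151 and 127 of 538 genes lower, while a block of 60 genes on it had medians of 0.27 and 0.41. Chromosome 19 had medians of 0.161 and 0.105 (148 and 103 of 399 genes higher), chromosome 13 had -0.087 and -0.146 (97 and 111 of 408 lower), and chromosome 18 had -0.098 and -0.088 (61 and 47 of 273 lower). Nrep and Apcdd1, named above as lower in APC-KO tumours, lie on chromosome 18. Their differences were far larger than its medians. Chromosome 6, with 569 genes, turned between the comparisons. It held more lower genes than an even spread without Dox (103 lower and 76 higher, adjusted p 2.62e-06 for lower) and more higher genes with Dox (110 higher and 58 lower, adjusted p 1.28e-06 for higher), by Fisher's exact test, one-sided. Chromosome 16 passed the same test for higher genes without Dox (84 of 345, adjusted p 8.57e-07) and not with Dox (0.222). Its medians were 0.11 and 0.077. Chromosomes 2, 8 and 12 passed it for higher genes with Dox (adjusted p 0.00341, 2.14e-06 and 9.07e-05) and not without. Their medians were 0.031, 0.05 and 0.076 without Dox, and 0.07, 0.083 and 0.107 with Dox. All these medians were above 0 in both comparisons, so a call in only 1 of them does not by itself show a shift with Dox. For Dox itself, the medians of chromosomes 2, 8, 12 and 16 were 0.012, -0.005, -0.073 and 0.041 in APC-WT tumours. In APC-KO tumours they were 0.063, 0.04, -0.026 and 0.023, and those of chromosomes 6 and 13 were 0.051 and -0.061. Whether these shifts differ between the genotypes was not tested. Genes of chromosome 3, 554 in all, were higher in APC-KO tumours without Dox (median 0.17; 226 higher and 20 lower) and had a median of 0.03 with Dox. With Dox in APC-KO tumours their median was -0.12, and 15 of the 56 genes that fell lay on that chromosome, against 2.8 for an even spread (Fisher's exact test, one-sided p 6.19e-08). Those 15 included S100a8, S100a9, Mgarp, Tiparp and H2ac19, and none of the 18 hypoxia genes lies there. Fisher's test counted genes as independent units, which neighbouring genes of the same tumours are not. Its p-values for all these chromosomes therefore do not measure the spread between tumours. The count of genes with Dox in APC-KO tumours was 0 without APC-KO Dox replicate 3. In windows of 30 neighbouring genes, 46 of 707 had a median beyond the limit of 0.178 from 1000 shuffles of gene order, and 45 of them had the same sign with Dox. These blocks were chosen after the values were seen.

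**Figure D3:**
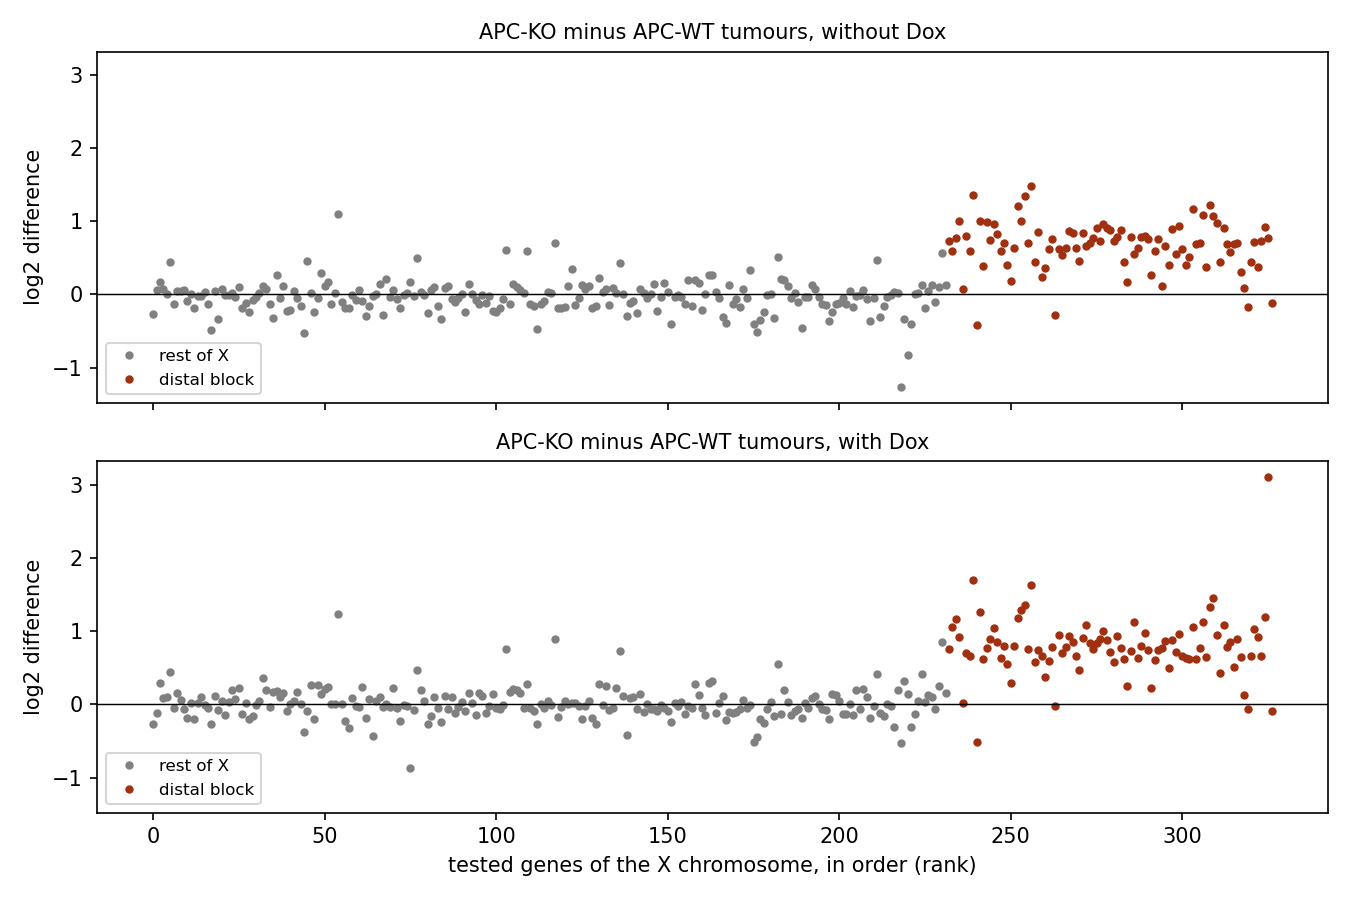
Log2 difference between APC-KO and APC-WT tumours for each tested gene of the X chromosome in chromosomal order, without Dox (upper panel) and with Dox (lower panel). The 95 genes of the distal block (red) had medians of 0.70 and 0.77, and the other 232 genes (grey) had medians of -0.03 and 0.00.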

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

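The tests of explanations in this part were chosen only after the results were seen, while the interaction itself was planned. With the preset correlation 9 lists passed for the difference between the genotypes in their change with Dox, and none with an estimated correlation (smallest adjusted p 0.146). The median interactions were 0.259 for cell cycle genes, -0.395 for hypoxia, -0.268 for glycolysis, -0.298 for chemokines and inflammatory cytokines, -1.483 for neutrophil markers, -0.213 for macrophage markers, 0.395 for interferon-stimulated genes, -0.283 for cholesterol biosynthesis and 0.134 for fibroblast markers. Of 100 splits of the Dox labels drawn within each genotype, from 200 possible, 31 gave as many lists, with up to 13 in another split, so chance was not excluded for this count. For genes, the real count was 0, which all 100 splits reach, so the splits do not test that count and chance was not excluded; the highest count in another split was 37.

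Probe sets without a single gene symbol were in no comparison of genes. Of 2968 above the floor, 9 changed with Dox in APC-WT tumours, 23 with Dox in APC-KO tumours, 620 between the genotypes without Dox, 488 with Dox, and 1 in the interaction.

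Hypoxia genes were lower with Dox in APC-KO tumours, with a median of -0.58. The lowest median of 2000 random lists of the same levels was -0.109, so genes of the same levels did not share the fall. The hypoxia list was picked for its small p against other genes, so this was no independent test of normalization. The macrophage list had a median of only -0.105, which argues against a general loss of macrophages as the whole cause. Its standard deviation of 0.338 is over its members and does not measure the spread between tumours. The neutrophil list had a median of -1.08, or -0.341 with no filter on level, so fewer neutrophils stay open as an explanation. An effect of Dox on tumours of either genotype stays open: hypoxia genes had a median of -0.24 in APC-WT tumours, and the adjusted p of the interaction was 0.1458 with an estimated correlation. Tumour size, necrosis and perfusion were not measured here, and an effect of the hairpin in APC-KO cells is an untested biological explanation.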

How the results depend on the processing

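One alternative, leaving out chromosomes 3 and X, was chosen after the data were seen, and gave 3, 40, 2336, 1959 and 0 genes for Dox in APC-WT, Dox in APC-KO, the genotypes without and with Dox, and the interaction. A planned change of pseudocount was not run, because the values are log2, and fitting only the groups compared equals the full fit for the interaction. Genes changed with Dox in APC-WT tumours numbered 0 with the mean of probe sets, 18 with only the groups compared and 653 with array quality weights; with Dox in APC-KO tumours 35, 36 and, without a trend, 29; array quality weights gave 3510 between genotypes with Dox and 13 in the interaction. Lists that passed with an estimated correlation numbered 0, 2, 0, 0 and 0 in that order, and by fry 0 in APC-WT, 2 between genotypes without Dox, 0 with Dox and 0 in the interaction. Between genotypes, 3 lists passed at the 75th percentile filter without Dox, and 12 with no filter and 10 with array quality weights with Dox. With 1 array left out, genes ranged from 0 to 417 (Dox in APC-WT, highest without APC-WT no-Dox replicate 3), 0 to 94 (Dox in APC-KO, lowest without APC-KO Dox replicate 3), 2142 to 2739 and 1288 to 2350 (genotypes without and with Dox) and 0 to 118 (interaction, highest without APC-WT no-Dox replicate 3), and lists from 7 to 11, 7 to 11, 4 to 9, 3 to 8 and 6 to 12. All called lists kept their direction in every alternative. The cause was not tested.

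Some named genes changed sign, none of which passed; Ddit4 was at -0.30 ± 0.31 in the interaction and the others were near 0. With Dox in APC-WT tumours Cd44 was at 0.009 with the mean of probe sets, Cox4i1 at 0.008 and Calr at 0.015 with quantile normalization, and Calr at 0.005 with array quality weights. With 1 array left out Cox4i1 ranged from -0.028 to 0.015, Vim from -0.031 to 0.012 and Calr from -0.023 to 0.038, and with Dox in APC-KO tumours Kyat3 from -0.108 to 0.01 and B2m from -0.035 to 0.024. In the interaction Lef1 was at -0.016 and Ccnd1 at -0.071 with the mean of probe sets, and with 1 array left out Ephb3 ranged from -0.016 to 0.12, Ccnd1 from -0.011 to 0.045, Slc3a2 from -0.094 to 0.076 and Ddit4 from -0.489 to 0.067. The cause was not tested.

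Whether replicate numbers pair the tumours is not stated in the labels, and the values do not settle it. Of 12 arrays, 5 correlated best with an array of their own number. Same-number correlations of deviations from the group means ran from -0.221 to 0.175. With the replicate block, 6 genes changed with Dox in APC-WT and 43 with Dox in APC-KO tumours.

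The 6 arrays of a comparison have 10 splits, too few for a share under 0.05. The real count of genes was reached by 1 split, the real one, in each comparison, and that of lists by 3, 7, 4 and 6 splits. The real and the highest other counts of genes were 3 and 0, 60 and 2, 2753 and 0, and 2205 and 0, and of lists 10 and 13, 7 and 9, 7 and 9, and 6 and 12.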

Other observations

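The tests of explanations and the choice of genes and blocks in this part were made only after the results were seen. Outside the fixed lists, the genes given here were picked from those that fell with Dox in APC-KO tumours because of a known response to low oxygen, with no test of such genes as a group and no count of those that did not fall. They were Mgarp (-1.28 ± 0.16), the vessel growth factor genes Angpt2 (-0.94 ± 0.14) and Pgf (-0.72 ± 0.10), the lipid droplet gene Hilpda (-0.88 ± 0.16) and the adenylate kinase gene Ak4 (-0.80 ± 0.15), with an adjusted p between 0.00631 and 0.0330.

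The lists not yet described did not pass. In the order of Dox in APC-WT, Dox in APC-KO, the genotypes without and with Dox, and the interaction, the medians were -0.02, -0.02, -0.05, -0.05 and 0.005 for p53 targets, -0.05, 0.16, 0.00, 0.07 and 0.08 for dendritic cells, -0.065, 0.03, 0.15, 0.25 and 0.07 for endothelial cells, -0.115, 0.05, -0.17, 0.02 and 0.02 for cecal epithelium, and -0.085, -0.365, -0.01, -0.35 and -0.34 for skeletal muscle. For p53 targets, endothelial, cecal epithelium and skeletal muscle lists the median differed in sign from the mean or the direction of the test in at least 1 comparison. Adjusted over the list alone, with Dox in APC-WT tumours 3 p53 targets were higher and 2 lower, and 2 cecal epithelium genes lower. With Dox in APC-KO tumours 1 dendritic cell gene was higher, and 1 p53 target, 2 endothelial and 1 cecal epithelium genes were lower. Without Dox, between genotypes, 4 p53 targets, 1 dendritic cell and 1 cecal epithelium gene were higher, and 2 of each of these lists lower. With Dox 1 dendritic cell, 5 endothelial, 1 cecal epithelium and 1 skeletal muscle genes were higher, and 2 p53 targets, 1 endothelial and 1 cecal epithelium gene lower. In the interaction 1 p53 target was lower and 1 cecal epithelium gene higher. Within cecal epithelium, the keratin gene Krt8 was at -1.35 ± 0.41 and -1.34 ± 0.41 with Dox in APC-WT and APC-KO tumours (adjusted p over all genes 0.162 and 0.189), and its interaction was 0.02 ± 0.59. The epithelial cadherin gene Cdh1 was lower by at least 1.25-fold with Dox in APC-WT tumours without passing (adjusted p 0.105), with all 3 Dox arrays under the floor. Fewer than 5 members were tested in the others: 3 aryl hydrocarbon receptor targets, 2 B and plasma cell, 1 mast cell, 3 smooth muscle, 2 enteric neuron and glia, 4 pancreatic acinar, 3 hepatocyte and 3 adipocyte markers, 1 sex chromosome gene and 0 red blood cell markers. Among these, 1 aryl hydrocarbon receptor target fell with Dox in APC-KO tumours, Tiparp (-0.53), 2 rose in APC-KO tumours without Dox and 1 with Dox, and 1 enteric and 1 pancreatic marker fell without Dox. The rest of the lists with fewer than 5 tested members had 0 members that passed.

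Single arrays without Dox stood apart from the others of their group in the median of the hypoxia list, relative to the mean of the APC-WT no-Dox arrays. They were APC-KO no-Dox replicate 1, at 0.448 against 0.191 and 0.184, and APC-WT no-Dox replicate 3, at 0.159 against -0.061 and -0.075. Without the former, 4 genes passed with Dox in APC-KO tumours, and the hypoxia list had a median of -0.609 and still passed. Without the latter, 417 genes passed with Dox in APC-WT tumours and 118 in the interaction. Both were found after leaving out each array in turn, and no cause was tested.

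Genes of the distal X block were higher in APC-KO tumours, by 0.70 without Dox. The block was found in the arrays without Dox, so the tests used those with Dox. The values argue against normalization of the arrays, since the highest median of level-matched random lists was 0.08 with Dox. The rest of X, with a median of -0.004 with Dox, cannot decide on sex or X inactivation of the host animals. Its genes were set apart from the block by the differences without Dox between the same cell lines. The X inactivation gene Xist lay between 4.16 and 4.74, under the floor on every array, and the Y chromosome gene Eif2s3y between 6.63 and 7.21. Both overlapped between the genotypes without and with Dox, and gave no sign of a difference in host sex. A regional copy-number difference between the injected cells is a candidate explanation: it needs the same shift with Dox, where the median was 0.773. A stable difference of another kind between the cell lines would need it too, so this does not favour copy number. With Dox the 3 APC-KO tumours lay between 0.68 and 0.765 against -0.077 to -0.003 in the 3 APC-WT tumours. DNA was not analysed here, and APC genotype cannot be parted from other differences between the cell lines.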
